A study of Mus musculus with 3 samples.

How the data were processed

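The data are RNA-seq libraries from bone-marrow-derived macrophages of C57BL/6J mice, which are primary cells grown out from marrow. Per the labels, the cells were stimulated for 10 min with 100 ng/ml Lipid A, the part of bacterial lipopolysaccharide that the receptor TLR4 recognises, and RNA of the chromatin fraction was sequenced as total RNA after ribosomal RNA depletion. Chromatin-fraction RNA is RNA that stays with the chromatin when the cell is fractionated, and it is rich in transcripts still being made or processed. There was 1 group of 3 libraries. The labels call them biological replicates 1, 2 and 3, give starting RNA amounts of 1 µg, 250 ng and 500 ng for them, and give a size range of 250 to 400. Each amount occurred in a single replicate, so amount and replicate cannot be separated. The labels also give the 3 libraries the same donor entry, so the spread between them, and any p-value based on it, may be partly technical. No unstimulated library is used here.

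For each library the authors deposited 3 tables. The gene table holds an estimated count, a TPM (the standard length-normalized transcript abundance) and a standard deviation of the count from read assignment for each gene, per the file headers. The first transcript table holds an estimated count and TPM for each transcript. Per the deposited readme files, both were derived from transcriptome alignments to mm10 with the GENCODE M21 annotation. The second transcript table holds estimated counts and TPM that the authors derived directly from the reads and an index of the same annotation, per the same readme files. The programs and versions are not given in the sources used here. The column names of the first set are those that RSEM writes and those of the second set those that kallisto writes. Whether strand was used in counting is not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. TPM of the gene table is relative to all listed RNAs, including short ones, so it depends on the share of the short RNAs.

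Each gene table held 81881 rows, of which 55536 named an annotated gene, 26248 had a numeric identifier, 96 were ERCC spike-ins and 1 was the phiX control. Rows that named no annotated gene were left out of library sizes and comparisons and held 1.16%, 0.459% and 0.351% of the estimated counts of replicates 1, 2 and 3. Genes were named, placed and typed with the GENCODE M21 annotation of the reference, which matched all 55536 identifiers. Coordinates are in mm10 and start at 1. Gene values of the second transcript table are sums over the transcripts of a gene. Aldoa had 2 gene identifiers, and the identifier with the higher mean TPM was used.

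The estimated counts assigned to genes were 15698066, 16005795 and 14386725 for replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.191, 0.187 and 0.209 CPM (counts normalized to library size). Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Rounded to whole numbers, the counts of any pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 30.5 for replicates 1 and 2, 24.6 for 1 and 3 and 13.1 for 2 and 3, so no library repeats another. This does not show separate animals or cultures, and the libraries were treated as replicates because the labels call them so.

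With a single group, comparisons were made between gene lists within each library. The lists, their tests and the alternatives were fixed before the data were examined. The 18 lists were immediate early genes, primary targets of NF-kB, late or secondary response genes, interferon stimulated genes, macrophage identity genes, TLR4 signalling genes, nuclear long non-coding RNAs, housekeeping mRNAs, proliferation genes, alternative activation genes and markers of 8 other cell types (neutrophils, T cells, B cells, erythroid cells, fibroblasts, mast cells, dendritic cells and osteoclasts). For each library the median of log2(TPM + 1) of a list was subtracted from that of another. The mean and SD over the 3 libraries were given, with a two-sided exact sign-flip permutation test of the 3 differences. The smallest p this test can give with 3 libraries is 0.25, so no such comparison could reach 0.05. With 6 such tests, the Benjamini-Hochberg adjusted p of the exact tests was 0.3 for the 5 comparisons of list medians and 1 for the retained intron share. The p of added alternatives was not adjusted. A difference on this scale understates the fold of low genes. A gene counted as detected at a TPM of 1 or more in all 3 libraries. The retained intron share of a gene was the percent of its TPM in transcripts annotated as retained_intron, among genes with a TPM of 1 or more and at least 1 such transcript.

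Spread between libraries was measured with edgeR 4.0.16 in R 4.3.3 as the common biological coefficient of variation, with an intercept only, on estimated counts rounded to whole numbers, after filterByExpr and TMM scaling. TMM-scaled CPM was also used to count genes that differed by 2-fold or more between 2 libraries, among genes with a mean of 10 or more counts, and to compute list shifts. The shift of a list is the median over its genes of the log2 ratio of a library to the mean of the other libraries, with 1 CPM added to each side. It is given as a percentile among 10000 random lists of the same size matched on mean expression in 40 bins, which describes these libraries and is not a p-value. It was computed for lists with 5 or more such genes, which left out alternative activation and was not done for the markers of other cell types. Shares of gene classes are percent of the estimated counts of all genes. The 2 quantifications were compared across genes with a TPM of 1 or more in either table. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

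Named genes followed a rule fixed in advance. In a list of more than 10 genes these are the 5 with the highest and the 2 with the lowest mean TPM, and any member an exception concerns. The rule also takes the 20 genes with the highest mean TPM among those over 200 bases long, and the 10 genes with the largest SD of log2(CPM + 1) among those with a mean of 100 or more counts. Genes outside the rule are marked where they appear, and 1 gene that the rule takes is not reported here.

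The steps were tested on simulated data made from the real means and library sizes with 200 changed genes. For the coefficient of variation, a simulated value of 0.173 was recovered as 0.171 over the 14876 unchanged genes, and as 0.188 when the changed genes were included, 15076 genes in all. For pair differences between replicates 1 and 3, 100% of the 50 genes changed 4-fold, and 3.48% of 15661 unchanged genes, differed by 2-fold or more. For list shifts, a simulated log2 shift of 1 over 20 genes was recovered as 0.96 and a shift of -1 as -1.01, while -2 came out as -1.80 and 2 as 1.87.

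Alternatives covered a pseudocount of 0.1, a filter on low list genes, the second transcript table, CPM without length normalization, list means, scaling with DESeq2 1.42.0 size factors, other count and TPM minimums, a prior of 0.1 CPM and leaving out each replicate in turn. After the data were seen, 5 more were added. These were the nuclear list without Gm26917, markers, late response genes and alternative activation genes detected in the second transcript table, the retained intron difference for each response list alone, list shifts against each other library alone, and TPM rescaled over RNAs other than short structural RNAs, genes of 200 bases or less, Gm26917, Gm42418 and Rmrp.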

Results

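Chromatin-fraction RNA of mouse bone-marrow-derived macrophages was measured 10 min after stimulation with 100 ng/ml Lipid A, in 3 biological replicates of 1 group. The libraries held 15698066, 16005795 and 14386725 estimated counts on annotated genes for replicates 1, 2 and 3. A TPM of 1 or more in all 3 libraries was reached by 13547 genes, of which 10120 were protein coding. The number was 20265 in the second transcript table. With TPM rescaled without short RNAs and Gm26917, Gm42418 and Rmrp, chosen after seeing the data, it was 16299. The RNAs kept for rescaling held 36.2%, 30.4% and 27.0% of TPM in replicates 1, 2 and 3, so detection counts depend on this share. Levels are the authors' TPM, given as mean ± SD over the 3 libraries. With no unstimulated library used here, a level does not show whether an RNA was induced.

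The first comparison asked which parts of the response to a TLR4 ligand were present on chromatin at this early time. Immediate early RNAs had a median TPM of 27.2 ± 17.8 (SD, n = 3), with 9.87 in replicate 3. This was no higher than TLR4 signalling genes, 27.6 ± 3.17, and below housekeeping mRNAs, 38.4 ± 9.22 (SD, n = 3 each). Late response RNAs were low, with a median of 0.128 ± 0.0580 (SD, n = 3), although 7 of 18 had a mean of 10 or more counts. Of the 22 immediate early genes, 20 were detected in every library and 17 had a mean TPM of 10 or more. Fos, a subunit of the AP-1 transcription factor (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273, plus strand), had a TPM of 179 ± 114 (SD, n = 3). Zfp36, which codes for an RNA-binding protein that speeds mRNA decay (ENSMUSG00000044786.6, chromosome 7, 28376784 to 28380253, minus strand), had 124 ± 70.3 (SD, n = 3). Junb, another AP-1 subunit, had a TPM of 109 ± 67.9, the phosphatase gene Dusp1 76.0 ± 36.3 and the transcription factor gene Klf6 66.1 ± 19.9 (SD, n = 3 each). Egr3 and Maff were the lowest members, with a TPM of 1.89 ± 1.03 and 1.75 ± 0.923 (SD, n = 3).

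Late or secondary response genes, which include cytokines made hours after stimulation, were detected in 3 of 18 cases. These were the chemokine gene Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518, minus strand) with a TPM of 3.41 ± 2.16, Acod1, which codes for the enzyme that makes itaconate, with 3.21 ± 1.99, and Il27 with 1.59 ± 0.367 (SD, n = 3 each). Saa3 and Mmp13 had a TPM of 1.01 ± 0.490 and 0.773 ± 0.261 (SD, n = 3). Il12a, Ifnb1 and Cxcl9 had 0 counts in all 3 libraries in the gene table, which allows up to 0.191, 0.187 and 0.209 CPM in replicates 1, 2 and 3. In the second transcript table Cxcl9 had a TPM of 0.481 ± 0.166 (SD, n = 3), so its 0 depends on the quantification, while Il12a and Ifnb1 had 0 there too. The immediate early list exceeded the late list by 4.41 ± 1.13 in median log2(TPM + 1) (SD, n = 3), and was higher in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest this test can give). The difference was 5.44, 4.60 and 3.19 in replicates 1, 2 and 3. It was 6.70 with a pseudocount of 0.1, 3.79 in the second transcript table and 3.82 with list means. When only genes with a TPM of 0.1 or more in some library were kept, it was 3.95.

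Primary NF-kB targets, which are genes bound and switched on by NF-kB without new protein synthesis, were also present. Of 24 genes, 21 were detected. Plk2, a polo-like kinase gene (ENSMUSG00000021701.8, chromosome 13, 110395046 to 110400844, plus strand), had a TPM of 109 ± 32.8 and the kinase gene Pim1 84.1 ± 31.3 (SD, n = 3). Birc3, an inhibitor of apoptosis gene, had a TPM of 47.9 ± 16.4, Nfkbia, which codes for the NF-kB inhibitor IkBa, 36.2 ± 36.4, and the chemokine gene Ccl4 27.7 ± 6.68 (SD, n = 3 each). Ptgs2 and Gpr84 were lowest with a TPM of 0.637 ± 0.206 and 0.297 ± 0.329 (SD, n = 3). The list median exceeded that of the late list by 3.57 ± 0.83 on the log2(TPM + 1) scale (SD, n = 3), in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest possible). It was 5.82 with a pseudocount of 0.1, 3.57 in the second transcript table and 2.90 with list means. When only genes with a TPM of 0.1 or more in some library were kept, it was 3.11.

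Interferon stimulated genes, which respond to type I interferon and act against viruses, stood above the NF-kB targets. Of 22 genes, 21 were detected. Stat2, a transcription factor of the interferon pathway (ENSMUSG00000040033.16, chromosome 10, 128270559 to 128292849, plus strand), had a TPM of 164 ± 63.0 and Oasl2 (ENSMUSG00000029561.17, chromosome 5, 114896936 to 114912234, plus strand) 156 ± 50.5 (SD, n = 3). Mx1 and the RNA sensor gene Ddx58 had a TPM of 108 ± 51.9 and 69.2 ± 22.1 (SD, n = 3 each). Isg15 and Isg20 were lowest with 4.24 ± 2.55 and 1.27 ± 0.679 (SD, n = 3). The NF-kB list minus the interferon stimulated list was -0.79 ± 0.21 in median log2(TPM + 1) (SD, n = 3) and below 0 in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest possible). Without length normalization the difference was -1.65, on log2(CPM + 1), and in the second transcript table it was -0.54.

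Genes of the TLR4 pathway itself were all detected, 23 of 23, with a median TPM of 27.6 ± 3.17 (SD, n = 3). The kinase gene Tbk1 (ENSMUSG00000020115.3, chromosome 10, 121546455 to 121586787, minus strand) had a TPM of 114 ± 18.7, the IkB kinase genes Chuk and Ikbkb 90.1 ± 21.5 and 75.4 ± 12, the co-receptor gene Cd14 86.0 ± 54.1 and Irf3 81.2 ± 15.4 (SD, n = 3 each). Ticam1 and Tirap, which code for adaptors, were lowest with 7.05 ± 1.32 and 3.76 ± 1.31 (SD, n = 3). The receptor gene Tlr4, named here after its value was seen, had a TPM of 28.0 ± 3.61 (SD, n = 3).

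**Figure D1:**
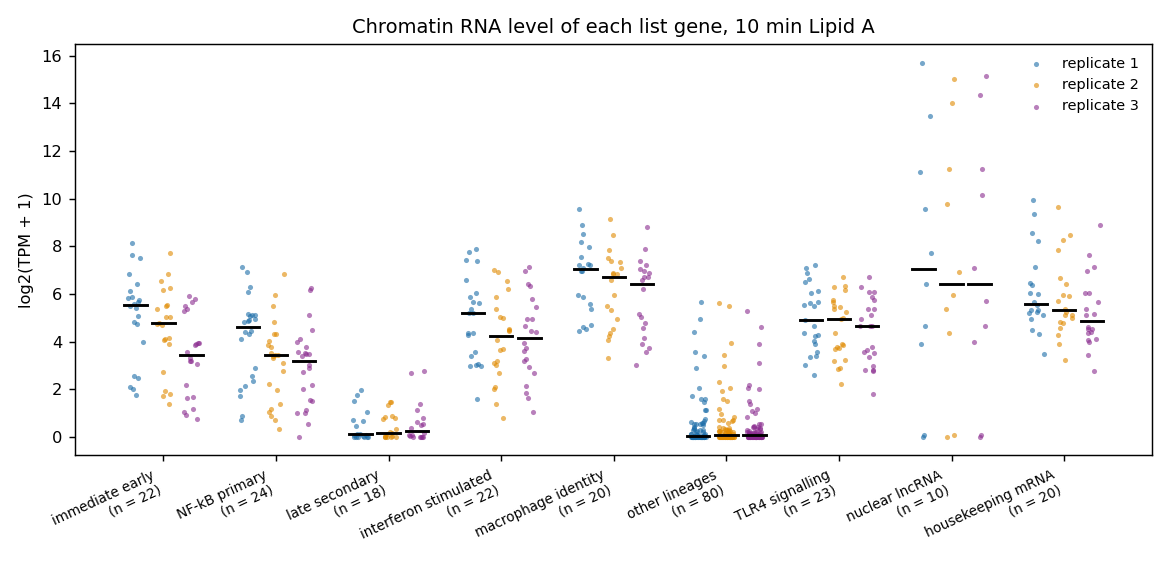
The vertical axis is log2(TPM + 1) and each point is a gene of the list named on the horizontal axis in one replicate, with colour for the replicate and a black bar at the list median. The medians of the late secondary and other lineage lists sit near 0, while the immediate early medians average 4.58 and the macrophage identity medians 6.72.

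The cell type named in the labels was compared with markers of 8 other lineages. All 20 macrophage identity genes were detected, and 11 of 80 markers of other lineages were. The lysosomal protease genes Ctsb (ENSMUSG00000021939.8, chromosome 14, 63122462 to 63145923, plus strand) and Ctsd had a TPM of 594 ± 161 and 356 ± 118, the lysozyme gene Lyz2 240 ± 115, the receptor gene for the growth factor M-CSF, Csf1r, 206 ± 74.0 and Laptm5 187 ± 54.9 (SD, n = 3 each). Fcgr1 and Cebpb were lowest with 16.6 ± 5.16 and 12.7 ± 8.28 (SD, n = 3). The macrophage list exceeded the other lineages by 6.67 ± 0.32 in median log2(TPM + 1) (SD, n = 3), in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest possible).

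No marker of neutrophils, fibroblasts or mast cells was detected in the gene table, out of 10 each. The fibroblast markers differed by library, seen only after the data were examined, with 0, 69 and 70 estimated counts in replicates 1, 2 and 3, of which Col1a1 had 0, 19 and 30. Among T cell markers Cd28 (ENSMUSG00000026012.2, chromosome 1, 60716800 to 60773359, plus strand) had a TPM of 44.7 ± 6.44, Cd4 7.97 ± 1.46 and Cd5 2.33 ± 0.714 (SD, n = 3 each), while Cd3e, Cd3g and Lck had a TPM of 0 in all 3 libraries. The B cell marker Cd22 had 1.8 ± 0.620 and the erythroid marker Alas2 7.94 ± 4.20, with the globin genes Hba-a1 and Hbb-bt at 0 (SD, n = 3 each). The dendritic cell markers Batf3 and Zbtb46 had 4.06 ± 2.00 and 1.43 ± 0.367 (SD, n = 3). Of the osteoclast markers, 4 were detected, namely Atp6v0d2 with 32.3 ± 10.3, Nfatc1 with 16.3 ± 3.53, Itgb3 with 3.55 ± 0.381 and Ctsk with 1.61 ± 0.385 (SD, n = 3 each). More markers of other lineages, 23 of 80, reached a TPM of 1 in all 3 libraries in the second transcript table, a comparison chosen after seeing the data. They included 1 each of neutrophils, mast cells and fibroblasts, namely Cxcr2 with 2.29 ± 0.130, Cpa3 with 1.52 ± 0.0848 and Thy1 (SD, n = 3 each). In that table the T cell marker Cd3d and the fibroblast marker Thy1 had a TPM of 11.4 ± 6.96 and 10.5 ± 2.07, against 0.03 ± 0.0265 and 0.0867 ± 0.150 in the gene table (SD, n = 3 each).

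Because the labels name the chromatin fraction, nuclear long non-coding RNAs were compared with housekeeping mRNAs. A library of another fraction or of whole cells is not used here, so these levels cannot show enrichment on chromatin. Long non-coding RNAs known to stay in the nucleus were among the most abundant RNAs over 200 bases long. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672, minus strand) had a TPM of 16324 ± 4850 and Neat1, the RNA scaffold of paraspeckles, 2357 ± 109 (SD, n = 3). Xist, which coats the inactive X chromosome (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254, minus strand), had 926 ± 192, and Firre 154 ± 46.4 (SD, n = 3). Mir99ahg, Airn and Kcnq1ot1 had 65.7 ± 17.3, 29.2 ± 9.14 and 16.0 ± 2.98 (SD, n = 3 each). Tsix had a TPM of 0.0500 ± 0.0100 (SD, n = 3). Meg3 had 0 counts in all 3 libraries in the gene table but a TPM of 0.417 ± 0.210 in the second transcript table (SD, n = 3). Gm26917 had the highest level of this list, 41098 ± 11058 (SD, n = 3). It lies on chromosome 17 at 39843013 to 39846341, and the annotated rRNA gene CT010467.1 lies beside it at 39846353 to 39848827. Gm42418 at 39846958 to 39848788 overlaps that gene on the other strand.

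Among 20 housekeeping mRNAs, all detected, the ferritin genes Fth1 and Ftl1 had a TPM of 753 ± 264 and 386 ± 236, Actb 284 ± 138, Eef1a1 221 ± 78.0 and Tmsb4x 102 ± 38.3 (SD, n = 3 each). Hprt and Pgk1 were lowest with 15.8 ± 2.64 and 8.08 ± 2.11 (SD, n = 3). The nuclear list exceeded the housekeeping list by 1.37 ± 0.22 in median log2(TPM + 1) (SD, n = 3), in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest possible). The difference was 0.76 without Gm26917, an alternative chosen after seeing the data, 3.27 when only genes with a TPM of 0.1 or more in some library were kept, and 4.13 without length normalization.

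Long non-coding RNAs took 29.0% ± 1.38 of the estimated counts (SD, n = 3), of which Gm26917 and Gm42418 together took 15% ± 1.99 of all counts and Malat1 and Neat1 10.6% ± 1.92 (SD, n = 3). Without Gm26917 and Gm42418, which lie beside or over the rRNA gene CT010467.1, the share was 14.0% ± 2.24 (SD, n = 3). Whether reads of these RNAs come from rRNA was not tested. Ribosomal protein mRNAs took 0.149% ± 0.0177 and mitochondrial genes 0.0559% ± 0.0320 (SD, n = 3), with 0.0926% in replicate 1 against 0.0407% and 0.0343% in replicates 2 and 3. Small structural RNAs took 2.63% ± 0.454 of the counts but 61.4% ± 6.62 of TPM, since TPM divides by length (SD, n = 3). The 20 highest RNAs over 200 bases long by TPM were led by Rmrp, the RNA of RNase MRP, which is annotated under 2 overlapping identifiers with a TPM of 51165 ± 12861 and 19847 ± 7429 (SD, n = 3). They also held Gm26917, CT010467.1, Malat1, Gm42418 and Neat1, the signal recognition particle RNA copies Rn7s1 and Rn7s2, Rn7sk, Rpph1, Scarna10, Scarna2, Gm22009, Gm25395, Snora73a, Snora73b, Snord17, Rnu3a and Rnu3b3. This order holds for TPM only, since TPM divides by length. In mean scaled CPM the Rmrp identifiers had 3891 and 1659, against 134208 for Gm26917 and 89345 for Malat1. Rn7s1 and Rn7s2 had the same TPM, 18241 ± 12714 each (SD, n = 3), with a read assignment SD of 3408 counts around a mean of 27194, so their levels cannot be separated.

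Chromatin RNA holds transcripts with introns still in place, so the share of TPM in annotated retained intron transcripts was compared between response genes and housekeeping genes. The share was large in both. The median was 61.5% ± 5.45 for the immediate early and NF-kB genes together and 58.8% ± 4.72 for housekeeping genes (SD, n = 3), against 46.6% ± 2.27 over all genes with such a transcript (SD, n = 3). Dusp1 had a share of 98.6% ± 0.480, Cd83, named after its value was seen, 91.3% ± 2.19, Fth1 97.3% ± 0.312, and Nfkbia 4.96% ± 2.5 (SD, n = 3 each). The difference of response minus housekeeping genes, 2.68 percentage points ± 4.82 (SD, n = 3), was within the spread of the libraries (two-sided exact sign-flip permutation test, p = 1). It was 8.24, -0.0764 and -0.115 percentage points in replicates 1, 2 and 3, -0.0956 without replicate 1, 0.396 in the second transcript table and -0.901 among genes with a TPM of 5 or more. The pooled lists differed when taken alone, a split chosen after seeing the data. Immediate early genes, 6 in number, had 69.7%, 72.2% and 62.4% in replicates 1, 2 and 3 against 56.9%, 64.2% and 55.3% for housekeeping genes, a difference of 9.30 ± 3.03 percentage points (SD, n = 3; two-sided exact sign-flip permutation test, p = 0.25, the smallest possible). NF-kB genes had 59.9%, 61.0% and 52.9%, a difference of -0.901 ± 3.37 (SD, n = 3; same exact permutation test, p = 0.75).

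The replicates were then compared with each other, gene list by gene list. Immediate early RNAs were lower in replicate 3. All 22 had less scaled CPM in replicate 3 than in the mean of the other replicates, with a median log2 ratio of -0.94 at percentile 0 of the matched random lists. Fos had 277, 269 and 75.5 scaled CPM in replicates 1, 2 and 3, Zfp36 414, 267 and 170, and Junb 263, 145 and 94.3. Egr1 had 76.7, 136 and 4.46 scaled CPM, a log2 ratio of -4.30 for replicate 3, and Klf6 had 168, 186 and 172, a log2 ratio of -0.04. Housekeeping mRNAs were also lower in replicate 3 in 18 of 20 cases, with a median log2 ratio of -0.37 at percentile 0 and Hsp90ab1 and Hprt as the exceptions. Actb had 330, 339 and 158 scaled CPM. Macrophage identity genes had a median log2 ratio of -0.29 in replicate 3 at percentile 0, with 17 of 20 lower. A ratio to the mean of the others can restate 1 extreme library, so single libraries were also compared, a step chosen after seeing the data. Against replicates 1 and 2 alone, replicate 3 had a median log2 ratio of -1.31 and -0.65 for immediate early genes (21 and 20 of 22 lower), -0.39 and -0.24 for housekeeping mRNAs and -0.47 and -0.13 for macrophage identity genes.

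Replicate 1, which had the largest starting amount of RNA, 1 µg, and the largest mitochondrial share of counts, 0.0926%, had more RNA of most protein-coding lists than the other replicates. NF-kB primary RNAs were higher in replicate 1 for 22 of 23 genes, with a median log2 ratio of 0.71 at percentile 100 and Il1a as the exception. Nfkbia had 93.0, 21.2 and 24.9 scaled CPM in replicates 1, 2 and 3, and Pim1 110, 64.2 and 69.7. The median log2 ratio of replicate 1 was 0.70 for immediate early genes (21 of 22 higher, all but Klf6), 0.53 for interferon stimulated genes (21 of 22, all but Ifit1), 0.37 for macrophage identity genes (18 of 20, all but Lpl and Trem2) and 0.31 for housekeeping mRNAs (19 of 20, all but Hsp90ab1), each at percentile 100. Against replicate 2 alone, replicate 1 had 0.39 for immediate early genes, 0.28 for macrophage identity genes and 0.21 for housekeeping mRNAs. Of these genes 16 of 22, 17 of 20 and 15 of 20 were higher, so a part of these ratios restates the low level of replicate 3. Against the mean of the others, TLR4 signalling genes had a ratio of 0.10 at percentile 90.4, and nuclear long non-coding RNAs -0.33 at percentile 0.130, with 6 of 8 lower and Gm26917 and Firre higher. The interferon stimulated genes were all lower in replicate 2 than in the mean of the others, 22 of 22, with a median log2 ratio of -0.44 at percentile 0, and were also lower there than in replicate 1 alone, 22 of 22, and in replicate 3 alone, 21 of 22. The NF-kB genes had -0.55 in replicate 2 and -0.35 in replicate 3, which restate the level of replicate 1, since replicate 3 against replicate 2 alone had -0.03, with 12 of 23 lower. Replicate 1 had 0.79 against replicate 2 and was the higher in 22 of 23 NF-kB genes against either replicate alone. The NF-kB ratio of replicate 3 to the mean of the others was -0.60 in the second transcript table.

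Proliferation genes stood apart in replicate 2. All 15 were higher there than in the mean of the other replicates, with a median log2 ratio of 0.83 at percentile 100. Replicates 1 and 3 had -0.46 and -0.65, which restate that level, since replicate 3 against replicate 1 alone had -0.09, with 10 of 15 lower. The replication clamp gene Pcna had 20.7, 28.6 and 20.0 scaled CPM in replicates 1, 2 and 3, Top2a, which codes for a topoisomerase of dividing cells, 19.8, 58.2 and 22.2, and Mki67 55.0, 171 and 68.7. By TPM, Aurkb had 6.25 ± 2.05, Mcm2 5.95 ± 0.754, and the lowest members Plk1 and Ccnb2 1.12 ± 0.703 and 0.813 ± 0.439 (SD, n = 3 each). Late response genes with enough counts, 7 in number, had a median log2 ratio of 0.72 in replicate 3 at percentile 100. Acod1 had 5.33, 4.36 and 16.5 scaled CPM and Ccl5 1.03, 0.589 and 3.00, from 16, 10 and 41 counts. In the second transcript table that median was 0.10 at percentile 87.0.

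**Figure D2:**
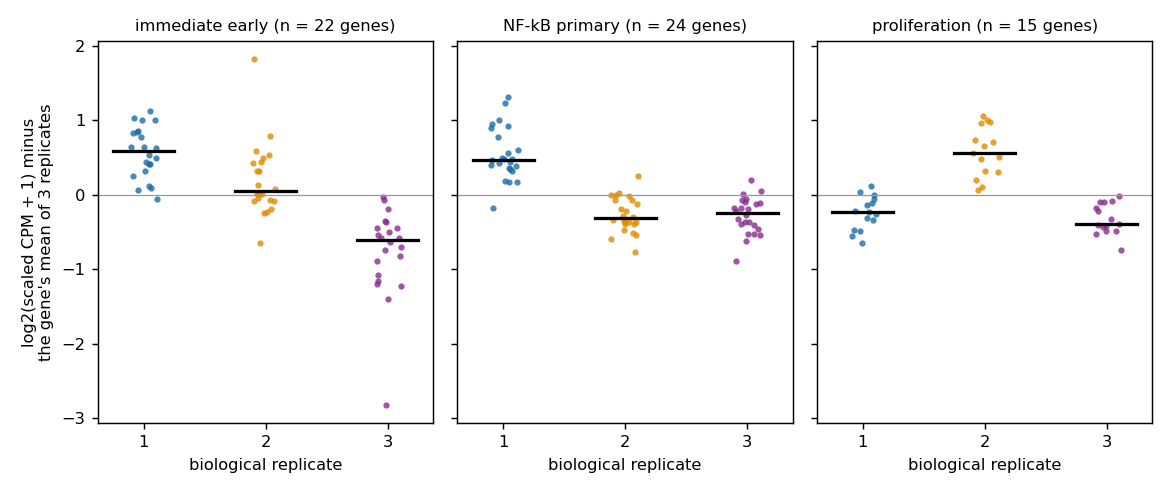
Each point is a gene of the immediate early, NF-kB primary or proliferation list, placed on the vertical axis by its log2(scaled CPM + 1) minus its mean over the 3 replicates, with the replicate on the horizontal axis and a black bar at the median. The 22 immediate early genes all lie below 0 in replicate 3, and the 15 proliferation genes all lie above 0 in replicate 2.

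Over all genes the common biological coefficient of variation was 0.172 (edgeR, 14894 genes). Across genes, which are not independent replicates, log2(TPM + 1) of the libraries had a Pearson r of 0.933 and Spearman rho of 0.931 for replicates 1 and 2, 0.928 and 0.930 for 1 and 3, and 0.946 and 0.942 for 2 and 3. Of 15871 genes with a mean of 10 or more counts, 1053 differed by 2-fold or more between replicates 1 and 2, 923 between 1 and 3 and 770 between 2 and 3. Each of these counts compares a pair of single libraries and has no test. Among genes with a mean of 100 or more counts the numbers were 205, 158 and 82 of 9757. In the second transcript table they were 2756, 3158 and 1025 of 25040, so the pair with the most such genes was 1 and 3 there and 1 and 2 in the gene table.

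The 10 genes with the largest spread between replicates were mostly short or mitochondrial RNAs. Egr1 was the response gene among them, with an SD of 2.48 in log2(CPM + 1). The snRNA Gm24497 had 0, 32.3 and 228 scaled CPM in replicates 1, 2 and 3, the U3 RNA Rnu3a (ENSMUSG00000065870.2) 110, 12.6 and 4.27, Gm23262 3.90, 41.5 and 96.5, Gm25776 4.24, 21.8 and 66.6 and the pseudogene Gm5641 0.438, 7.58 and 18.5. The mitochondrial mt-Co3 had 43.5, 0.110 and 0.112 scaled CPM, mt-Co2 0, 23.8 and 12.9 and mt-Atp6 14.5, 0 and 10.6. For mt-Co3 the read assignment SD averaged 265 counts around a mean of 227 counts, for mt-Co2 150 around 194, for mt-Atp6 102 around 124 and for Gm24497 676 around 1223, so these levels are uncertain. Gm26992 had 53.6, 0 and 7.27 scaled CPM. It lies on the plus strand of chromosome X at 103422010 to 103481705 and overlaps Xist on the other strand.

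Gene totals from the second transcript table were compared with those of the gene table. Across genes with a TPM of 1 or more in either table, which are not independent replicates, log2(TPM + 1) had a Pearson r of 0.680 ± 0.0214 and a Spearman rho of 0.621 ± 0.0217 (SD, n = 3). Over all genes compared, 7745 of 21859, 9969 of 23270 and 9961 of 22331 differed by 2-fold or more in replicates 1, 2 and 3, and 238, 254 and 221 of these were higher in the gene table. Of the list genes, 27, 44 and 41 of 190, 198 and 189 did, and all of these were higher in the second table. TPM is relative to all RNAs of a table, so it also depends on the share of short RNAs. Small structural RNAs took 61.4% ± 6.62 of gene-table TPM (SD, n = 3). Protein-coding genes took 65.9% ± 1.33 of gene-table counts and 63.0% ± 1.70 of second-table counts (SD, n = 3 each). How far this share accounts for the excess in TPM was not tested. Nr4a1 and Ccl3, named after their values were seen, had a TPM of 68.5 ± 36.0 and 59.5 ± 19.5 in the second table against 29.4 ± 21.3 and 21.2 ± 11.7 in the gene table (SD, n = 3 each). The second table held 1.53, 1.76 and 1.73 times as many estimated counts as the gene table in replicates 1, 2 and 3. Among genes with a TPM of 10 or more r was 0.394.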

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

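Rows of the gene tables that named no annotated gene held reads, above the 3 counts that a count of 0 allows. The phiX control sequence, which is commonly added to sequencing runs, had 184450, 73769 and 50701 estimated counts in replicates 1, 2 and 3, or 1.16%, 0.459% and 0.351% of each total. Rows with numeric identifiers, 26248 in number, had 26, 33 and 30 estimated counts in all, and what these identifiers stand for was not examined. The 96 ERCC spike-in rows had 0 counts in each library.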

How the results depend on the processing

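The values without Gm26917, with rescaled TPM, for markers, late and alternative activation genes detected in the second table and for retained introns by list were chosen after seeing the data. Under alternatives set before the data were examined, tested differences kept their sign in 43 cases, 8 of which moved by over 1.5 times, and changed it in 2. Values without a test stayed within 1.5 times for counts of genes, or within 1 SD between replicates, between random lists for list shifts, or between the values with a replicate left out for the coefficient of variation, in 97 cases. They moved further in 28 and changed sign in 2. Every comparison of list medians kept its sign in all alternatives run, but no exact test of 3 libraries could reach p = 0.05. With rescaled TPM, immediate early minus late genes was 5.72 and NF-kB minus late genes 4.85. On that scale NF-kB minus interferon stimulated genes was -0.83, macrophage identity minus other lineages 8.24 and nuclear minus housekeeping RNAs 1.38. Markers detected in the second table were 1 for neutrophils, fibroblasts and mast cells each, 5 for T cells, 2 for B cells, 3 for erythroid cells, 4 for dendritic cells, 6 for osteoclasts and 23 of 80 in all. The retained intron difference was 0.396 in the second table, -0.901 among genes with a TPM of 5 or more, and ranged from -0.0956 to 4.08 percentage points when each replicate was left out. It was 9.30 for immediate early genes alone and -0.901 for NF-kB genes alone. The sign of the pooled value depends on replicate 1. With a mean of 100 or more counts, 2-fold pair differences were 205, 158 and 82 of 9757 genes. In the second table they were 2756 for replicates 1 and 2, 3158 for 1 and 3 and 1025 for 2 and 3, of 25040 genes. A prior of 0.1 CPM gave list shifts of -1.11 for immediate early genes in replicate 3, -0.75, -0.47 and 1.43 for late genes in replicates 1, 2 and 3, -0.52 for interferon stimulated genes in replicate 2, and 1.07 and -0.77 for proliferation genes in replicates 2 and 3. The second table gave 0.87 and -0.038 for immediate early genes in replicates 1 and 2, where the latter was 0.07 in the gene table, -0.60 for NF-kB genes in replicate 3, -0.18 and 0.10 for late genes in replicates 1 and 3, -0.17 for interferon stimulated genes in replicate 3, 0.20 for TLR4 genes in replicate 1, and -0.31 and -0.51 for proliferation genes in replicates 1 and 3. With DESeq2 size factors the shift of TLR4 genes in replicate 3 was 0.0032, on the other side of 0 from -0.000255. Measured by TPM, ribosomal protein, small structural and long non-coding RNAs took 0.199%, 61.4% and 10.4%, and small structural RNAs took 3.70% of second-table counts. The correlation of the 2 quantifications was 0.394 at a TPM of 10 or more and 0.559 with a pseudocount of 0.1. The coefficient of variation was 0.206 in the second table and 0.138 to 0.197 with each replicate left out. Except where construction shows it, the cause was not tested. Depth limits genes under 0.191, 0.187 and 0.209 CPM.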

Other observations

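Of the tests given here, those against mature mRNA, that by exon number and its split to protein-coding genes were chosen after their results, or the values they rest on, had been seen. Markers of alternative activation, a state linked to the cytokine IL-4, were mostly near the floor in the gene table, with 3 of 10 detected. The lectin receptor genes Clec7a and Clec10a had a TPM of 56.3 ± 21.6 and 25 ± 16.4, and the arginase gene Arg1 2.00 ± 0.646 (SD, n = 3 each), while Retnla and Ccl17 had a TPM of 0 in all 3 libraries.

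The 5 protein-coding genes with the highest mean TPM were named after their values were seen. Gpnmb, a membrane glycoprotein gene, had a TPM of 1381 ± 323, the inhibitory receptor gene Lilrb4a 1017 ± 170, the proton pump subunit gene Tcirg1 958 ± 204, the lysosomal activator gene Psap 945 ± 360 and Rsrp1 890 ± 234 (SD, n = 3 each). Of 4 Y-linked genes looked at, Uty and Eif2s3y had 0 counts in all 3 libraries, and Kdm5d and Ddx3y had 0.0589 scaled CPM each in replicate 2, under the floor, and 0 in replicates 1 and 3.

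Immediate early RNAs were lower in replicate 3. A bias by transcript length is argued against, since the median shift of -0.94 lay at percentile 0 of random lists matched on expression and length together, whose central 95% ran from -0.08 to 0.10. Less mature mRNA in that preparation stays open, since the retained intron share cannot decide it. Macrophage identity genes had a median share of 32.9% against 68.1% for immediate early genes, from the 8 and 6 genes with such transcripts. The immediate early shift was the lower by -0.66, with a 95% bootstrap interval over genes of -1.17 to -0.42. Such intervals hold the spread between genes and not that between preparations. Yet housekeeping mRNAs, with a share of 58.8% against 46.6% for all genes, also fell in replicate 3. Over those 6 and 8 genes alone the difference was -0.91 with an interval of -1.58 to -0.14. Against replicate 2 alone it was -0.41 for these genes, with -1.55 to -0.006. Against the 1153 genes at or below the lower quartile of the share in every library it was -0.98, with -1.47 to -0.79. Those 1153 genes did not fall in replicate 3, with a median shift of 0.04, against -0.02 for genes at or above the upper quartile. The former minus the latter was 0.06, with an interval of 0.04 to 0.08. Genes with a high share were therefore slightly lower, by far less than the immediate early shift. Against replicates 1 and 2 alone the difference from macrophage identity genes was -0.84, with -1.25 to -0.32, and -0.52, with -0.99 to -0.27, while a part shared with housekeeping mRNAs, which had a shift of -0.37, stays open, the starting amount of RNA is confounded with the replicate, and no biological explanation was tested.

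NF-kB primary RNAs were higher in replicate 1. The shift of 0.71 lay at percentile 100 of random lists matched on expression and length, whose central 95% ran from -0.12 to 0.17, which argues against length bias. More mature mRNA in that preparation stays open, although the NF-kB shift exceeded that of macrophage identity genes, 0.37, by 0.34 with a 95% bootstrap interval over genes of 0.11 to 0.66, and these had a median retained intron share of 32.9% against 57.9% for NF-kB genes. Against replicate 2 alone the difference was 0.51, with an interval of 0.22 to 0.75, but against replicate 3 alone it was 0.18, with -0.06 to 0.71, which includes 0. Ribosomal protein mRNAs had a median shift of 0.24 in replicate 1, with 69 of 81 higher, so a part may come from the preparation, the starting amount of RNA is confounded with the replicate, and no biological explanation was tested.

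Gene totals differed between the 2 transcript quantifications. Reads crossing exon-intron borders would make the second table exceed the first more in genes with many exons. Over all genes the median log2 ratio was instead 0.75 lower in genes of 10 or more exons than in single-exon genes. That difference of -0.75 had a 95% bootstrap interval of -0.81 to -0.68. Among protein-coding genes single-exon genes were the lowest, with medians of -0.14, 0.51, 0.52 and 0.41 for 1, 2 to 3, 4 to 9 and 10 or more exons. The exon groups were not matched for gene class, so this test cannot decide. Reads of an opposite-strand gene stay open. Of the 3935 genes at least 4-fold higher in the second table, 4.98% overlapped exons of such a gene, against 23.3% of the 13695 genes within 2-fold. The ratio was 0.214 with a 95% interval of 0.185 to 0.244, not the excess that such reads would give. It cannot decide, since the sets were not matched for gene size or class. Of the higher genes 18.0% were protein coding, against 71.7% of those within 2-fold. Intron reads of a surrounding gene on the same strand remain a candidate explanation for a part, with 21.8% against 13.6%, a ratio of 1.61 with an interval of 1.49 to 1.73. The same lack of matching limits this ratio. Of the higher genes, 36.8% were small RNAs, against 1.5% of those within 2-fold. Neither a difference in the short RNA share of TPM nor any biological explanation was tested.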
